A study of Mus musculus with 22 samples.

How the data were processed

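Kidney tissue of 22 male wild-type C57BL/6JRj mice was sequenced from the 3′ ends of polyadenylated transcripts with the QuantSeq 3′ FWD kit, 1 library per animal. The groups, taken from the labels, were young mice of 4 months (n = 6), old mice of 21 months (n = 8) and old mice given nicotinamide in the diet (n = 8; 200 mg per kg body weight per day, 1.6 g per kg food, 14 weeks). The deposited table held raw read counts per mouse Ensembl gene, which per the labels the authors made with STAR and HTSeq; versions, trimming, duplicate handling and the strand setting are not given in the sources used here. The labels name GRCh38, a human genome build, while all gene identifiers in the table are of mouse, so no coordinates are printed. The table had 55487 gene entries and 5 HTSeq summary entries for 22 columns, of which 0 were left without a sample; the count of reads with more than 1 alignment was 0 in each column. Symbols came from GENCODE M21 and covered 55141 identifiers; the identifiers without a symbol held 0.0148% of the gene counts.

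Depth was 3351065 to 8319865 gene counts per library. Whether PCR copies were removed before counting is not given, so counting error is taken as a lower limit of the error. Within a group, all 71 pairs of libraries differed by more than counting error (chi-square per degree of freedom 5.50 to 39.4), which rules out a copied library. The replicate numbers were checked for pairing between groups. The 20 pairs of libraries with equal numbers had correlations of −0.082 to 0.0587 over genes centred on group means, and 0 lay above 0.1, so no pairing was modelled. In 5 of the pairs a library was the best match of its own number, a count that was not set against chance. A block for the replicate number was run as an alternative.

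Genes were filtered with filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total count 15, smallest group 6), which kept 14683 genes with 99.75% of the counts. All 22 libraries entered 1 quasi-likelihood fit in edgeR with TMM factors, robust dispersions and no covariates, and each comparison was a contrast of 2 groups, tested two-sided. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are given on the log2 scale with a standard error (SE). It was derived from the test, as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Levels are counts per 1000000 counts of the library total scaled by its TMM factor (CPM) with the standard deviation (SD). Each adjusted p of a single gene is from edgeR unless another tool is named. Old against young and nicotinamide against old were the main comparisons; nicotinamide against young was secondary and shares its libraries with both.

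The gene lists (39 lists, 678 genes, of which 597 were tested and 9 had no entry under their symbol) were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives not described as added. They covered nicotinamide and NAD synthesis; nicotinamide clearance and NAD consumption; methionine and one-carbon metabolism; senescence and its secretory phenotype; fibrosis and extracellular matrix; tubular injury; markers of the proximal tubule segments S1 and S2 and of S3, of the loop of Henle, of the distal and connecting tubule, of collecting duct principal cells, intercalated cells, podocytes, endothelium, mural and juxtaglomerular cells, T and natural killer cells, B and plasma cells, macrophages and dendritic cells, neutrophils, adipocytes, adrenal gland and urothelium. The others were MHC class II, lymphoid aggregates, complement, interferon response, blood cells and haemoglobin, mitochondrially encoded genes, nuclear genes of oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, androgen-dependent kidney genes, circadian clock, immediate early and heat shock genes, NRF2 targets, the unfolded protein and integrated stress response, proliferation, the longevity and vitamin D axis, and DNA damage with p53 targets. Some genes stood in more than 1 list (C1qa, C1qb and C1qc in the macrophage and complement lists, Acta2 in the fibrosis and mural lists, Ccl2 in the senescence and injury lists, Cfd in the adipocyte and complement lists). Others were Kap, Cyp7b1 and Slco1a1 in the S3 and androgen-dependent lists, and Slc34a1 and Slc34a3 in the S1 and S2 and longevity lists. Calb1, Trpv5 and S100g stood in the distal tubule and longevity lists. Further overlaps are not listed. A list needed 5 tested members, which left 37. Each was tested with camera (limma 3.58.1) with an inter-gene correlation estimated per list, adjusted over the 37 lists. Camera with a preset correlation of 0.01 and fry, which tests whether a list's genes move one way without comparing them with other genes, were the alternatives. All values given for both are adjusted over the 37 lists too. The neutrophil list had 3 tested members and a highest group mean of 4.09 CPM, the adrenal list 1 tested member and 1.72 CPM, and neither was tested.

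Named genes followed a fixed rule: Nnmt; the 8 largest rises and the 8 largest falls that passed with a mean of at least 5 CPM in the higher group; the 4 genes of lowest p; and for each list up to 2 passing members per direction. Predicted and clone names and variable segments of immunoglobulins and T cell receptors were excluded. Where fewer than 10 genes passed, all passing genes under the symbol rule were named, and the 5 genes of lowest p per direction as values. Genes outside this rule are named as chosen after their values were seen, and some genes that the rule selects are not reported here.

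For single measures (Nnmt in CPM, shares of reads, and the score of each list, which is the mean over its tested members of log2 CPM with a prior count of 2, centred per gene), groups were compared by exact two-sided permutation tests over all 3003 splits of 8 and 6 or 12870 of 8 and 8 libraries, with 95% intervals by inverting the test; these were added after the data were examined. The smallest p these tests can give is 0.000333 for 8 against 6 and 0.000155 for 8 against 8. Adjusted values cover the 37 list scores or the 6 library measures of a comparison. Correlations between list scores used values centred on group means and 100000 permutations within groups.

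On simulated data with the fitted dispersions, the edgeR test recovered, for old against young, 43.3%, 64.2% and 81.8% of genes changed 1.5-fold, 2-fold and 4-fold. For nicotinamide against old the shares were 28.4%, 64.2% and 95.5%, and for nicotinamide against young 31.3%, 77.6% and 89.4%. False calls were 3.08%, 3.10% and 5.71% of the calls in these simulations. The permutation test gave p below 0.05 in 6 of 100 simulated data sets without a difference at 8 against 6, and in 2 of 100 at 8 against 8.

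Alternatives were DESeq2 size factors or upper-quartile factors in edgeR, no low-count filter, another filter (10 counts in 6 libraries, 14747 genes), a fit of only the 2 groups compared, a block for the replicate number, DESeq2 1.42.0, limma-voom with quality weights, and each library left out in turn. Those chosen after seeing the data left out 4 libraries (young replicate 6, old replicate 7, nicotinamide replicates 1 and 7) or 3 ribosomal RNA genes (CT010467.1, mt-Rnr1, mt-Rnr2), or single kidneys for the list scores under nicotinamide. The software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The human data named in the series title are not analysed here.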

Results

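Gene expression was measured as read counts in the kidneys of 22 mice: 6 young, 8 old and 8 old with nicotinamide, the amide form of vitamin B3 and a precursor of NAD. Total gene counts per kidney were 3351065 to 7184997 in young, 5443099 to 7519169 in old and 5663649 to 8319865 in nicotinamide-treated kidneys. Young replicate 6 had the lowest depth and nicotinamide replicate 2 the highest. The number of genes with a count was 728 higher in old than in young kidneys (95% interval 345 to 1118; exact permutation p = 0.00133, adjusted p = 0.00400). Reads that fell in no annotated gene made up 20.5% ± 1.30 (SD) of the assigned and unassigned reads in young, 22.8% ± 1.25 in old and 21.6% ± 1.41 in nicotinamide-treated kidneys. Old kidneys had 2.30 percentage points more of them than young (exact permutation p = 0.00733, adjusted p = 0.0110), and the difference of −1.25 points with nicotinamide did not pass (exact permutation p = 0.0845, adjusted p = 0.169). Ribosomal RNA also took a larger share of the libraries of old than of young kidneys. The difference was 0.834 percentage points for the gene CT010467.1 (95% interval 0.272 to 1.45; exact permutation p = 0.00699, adjusted p = 0.0110) and 1.25 points for mt-Rnr1 with mt-Rnr2 (0.622 to 1.89; exact permutation p = 0.000666, adjusted p = 0.00400), with 8 of 8 old kidneys above the young mean in both.

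The first principal component held 15.1% of the variance and separated the 6 young kidneys from the other kidneys. On the second (6.96%), nicotinamide replicate 7 lay at −62.2 and no other library below −21.0. Old replicate 7 and nicotinamide replicate 1 lay together at the high end of both. Marker lists put values on these kidneys: nicotinamide replicate 7 had the highest T cell score, nicotinamide replicate 1 had 60.7 CPM of the fat hormone gene Adipoq and 133 CPM of the injury marker Lcn2, and old replicate 7 had 42.1 CPM of the urothelial marker Psca.

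**Figure D1:**
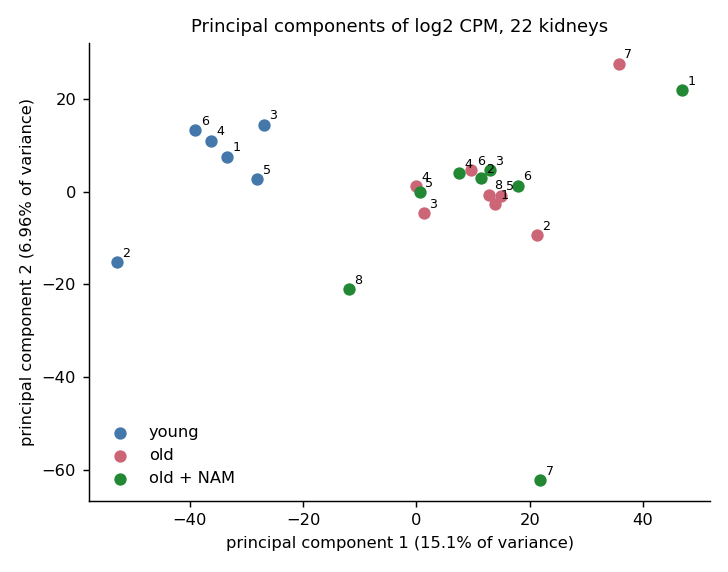
Principal components 1 and 2 of log2 CPM over the tested genes, 1 point per kidney with its replicate number, coloured by group. The young kidneys lie at −26.9 or lower on component 1, and nicotinamide replicate 7 stands alone at −62.2 on component 2.

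The comparison of old with young kidneys asks how the kidney differs between both ages. Old kidneys held more transcripts of immune cells, of extracellular matrix and of injured tubules. They held fewer of intercalated cells, a list call of an adjusted p = 0.0438 that was lost in several alternatives. H2-Aa, which presents antigen on MHC class II, rose from 136 ± 16.4 to 300 ± 61.1 CPM (log2 fold change 1.14 ± 0.12 SE, adjusted p = 1.16e-07, n = 6 and 8). Havcr1, the tubular injury marker KIM-1, rose 5.69-fold (2.51 ± 0.46, adjusted p = 0.00142), from 1.78 ± 1.63 to 10.3 ± 4.82 CPM. Mgp, an inhibitor of calcification in the matrix, rose 2.06-fold (1.04 ± 0.14, adjusted p = 3.20e-05). Ctxn3, a small membrane protein of kidney and brain, fell 11.8-fold (−3.56 ± 0.49, adjusted p = 3.69e-05), from 13.9 ± 4.21 to 1.15 ± 0.782 CPM.

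Among the largest rises were 3 interferon-inducible genes of 1 family, Ifi211 (2.88 ± 0.64), Ifi204 (2.61 ± 0.59) and Ifi213 (2.36 ± 0.59), with adjusted p of 0.00509, 0.00717 and 0.0139. The chemokine Ccl8 (3.27 ± 0.91, adjusted p = 0.0340) and Jaml, an adhesion molecule of leukocytes (2.19 ± 0.49, adjusted p = 0.00505), also rose. The antibody heavy chains Ighg1 (3.81 ± 1.13, adjusted p = 0.0466) and Ighm (2.58 ± 0.65, adjusted p = 0.0196) rose as well. The largest falls after Ctxn3 were Synpr, a synaptic vesicle protein (−3.17 ± 0.65), Popdc3, a cAMP-binding membrane protein (−2.88 ± 0.68), and Cntnap5a (−2.10 ± 0.44). They were followed by Nudt11 (−1.77 ± 0.40), the steroid reductase Srd5a2 (−1.38 ± 0.42), Mogat2, an enzyme of triglyceride synthesis (−1.35 ± 0.36), and the matrix protease Adamts15 (−1.32 ± 0.34), with adjusted p of these 7 genes between 0.00212 and 0.0401. Lowest in p, beside H2-Aa, were Serpine2, an inhibitor of serine proteases (1.17 ± 0.13), Irf8, a transcription factor of myeloid and B cells (1.13 ± 0.13), and Pou2f2, a transcription factor of B cells (1.47 ± 0.18). All 8 old kidneys lay on the stated side of the young median for each of these genes except Ighg1, where 7 did. The calls of Ighg1, Ccl8, Srd5a2 and Adamts15 were lost in 17, 8, 9 and 3 of 32 alternatives, with highest adjusted p of 0.396, 0.213, 0.112 and 0.120. Ighm lost its call in 2 (highest adjusted p 0.105). Ifi211, Ifi204 and Nudt11 lost theirs in 1 each, limma-voom (adjusted p 0.0850, 0.0857 and 0.0503 there). In 1 kidney, young replicate 3, there were 87.4 CPM of Adamts15 against 14.0 to 27.8 CPM in the other young kidneys. Over the 32 alternatives the log2 fold change of Adamts15 ranged from −1.47 to −0.71, so its place among the largest falls is uncertain.

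Macrophage and dendritic cell markers rose together: 16 of 22 tested members passed, all upward, and 21 adjusted over the list alone (median 1.40, adjusted p = 0.00142 with an estimated correlation). Fcer1g, a signalling chain of Fc receptors, rose 2.48-fold (adjusted p = 7.84e-06), and Cx3cr1, the fractalkine receptor of resident macrophages, 3.02-fold (adjusted p = 8.47e-05). MHC class II genes rose in 6 of 8 members, and in 8 adjusted over the list alone (median 1.15, adjusted p = 0.00142 with an estimated correlation). Complement genes rose in 9 of 16 members, and in 11 adjusted over the list alone (median 1.28, adjusted p = 0.0158 with an estimated correlation). Among them C1qb rose 2.89-fold. Lymphocyte lists had medians as high and did not pass with an estimated correlation, while fry gave 0.0102 for T cells and for B cells and 0.00799 for lymphoid aggregates. Their scores were higher in old by 1.29, 1.41 and 1.25 (exact permutation adjusted p = 0.00137, 0.0104 and 0.00435), with 8 of 8 old kidneys above the young mean in each. T and natural killer cell markers had 2 of 13 members past, 2 adjusted over the list alone (median 1.41, adjusted p = 0.145 with an estimated correlation), the adhesion molecule Cd2 and the coreceptor Cd4. B and plasma cell markers had 5 of 17 members past, 7 adjusted over the list alone (median 1.33, adjusted p = 0.145 with an estimated correlation), with the antibody light chain Igkc at 619 ± 233 and 2021 ± 668 CPM (1.71 ± 0.42, adjusted p = 0.0168). Lymphoid aggregate genes had 1 of 5 past, the homing receptor Ccr7, 2 adjusted over the list alone (median 1.41, adjusted p = 0.145 with an estimated correlation). Interferon response genes had 4 of 23 past, 14 adjusted over the list alone (median 1.0, adjusted p = 0.184 with an estimated correlation), with the antiviral Bst2 at 1.71 ± 0.44 and the interferon brake Usp18 at 1.97 ± 0.50. Without the 4 kidneys 11 of 22 interferon genes passed. Without nicotinamide replicate 7, which takes part only in the estimate of the spread, the T cell and interferon lists passed (adjusted p = 0.0152 and 0.0399). For adipocyte scores no difference between young and old kidneys was found (0.0737, 95% interval −1.40 to 1.58, exact permutation p = 0.906). That interval is wide and leaves a difference of either sign open. Urothelial scores were higher in old by 1.01 (0.11 to 2.05, exact permutation adjusted p = 0.0311), with 8 of 8 old kidneys above the young mean. Young replicate 2 (−2.58) and old replicate 7 (2.28) stood apart and account for part of this difference, and the former lowers the young mean. The other young kidneys lay at −0.90 to −0.12 and the other old kidneys at −0.67 to 0.25, so they overlapped. The macrophage, MHC class II and complement lists held 16, 6 and 11 members past without the 4 kidneys that stood apart or had the lowest depth.

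Matrix, injury and senescence lists rose too. Fibrosis and extracellular matrix genes rose in 17 of 32 members, and in 23 adjusted over the list alone (median 0.74, adjusted p = 0.00826 with an estimated correlation). Bgn, a proteoglycan of the matrix, rose 1.72-fold (0.78 ± 0.10, adjusted p = 6.68e-07). Without the same 4 kidneys, 11 of 31 members passed. Tubular injury genes rose in 14 of 26 members, and in 18 adjusted over the list alone (median 0.81, adjusted p = 0.00912 with an estimated correlation), with the adhesion molecule Vcam1 2.97-fold (1.57 ± 0.20, adjusted p = 1.45e-05) and the hyaluronan receptor Cd44 2.72-fold (1.44 ± 0.28, adjusted p = 0.00107). Senescence and secretory genes rose in 7 of 24 members, and in 11 adjusted over the list alone (median 0.57, adjusted p = 0.00530 with an estimated correlation). The members with the lowest p were the membrane protease Mmp14 (1.02 ± 0.16, adjusted p = 8.08e-05) and the adhesion molecule Icam1 (0.96 ± 0.19, adjusted p = 0.00135), both also made by leukocytes or stroma. The cell cycle inhibitor Cdkn1a, chosen after its value was seen, stood at 39.0 ± 10.1 and 59.2 ± 11.7 CPM (0.60 ± 0.20, adjusted p = 0.0657) and did not pass. DNA damage and p53 targets had 2 of 22 members past, Phlda3 and Trp53inp1, and 3 adjusted over the list alone (median 0.23, adjusted p = 0.0868 with an estimated correlation; 0.0481 without nicotinamide replicate 4). The calls of Phlda3 and Trp53inp1 were lost in 3 and 4 of 32 alternatives (highest adjusted p 0.0709 and 0.0734), and 0 of 22 members passed in edgeR without the 4 kidneys. Proliferation genes had 0 of 13 members past in edgeR and 0 adjusted over the list alone (adjusted p = 0.387 with an estimated correlation, fry 0.0671).

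**Figure D2:**
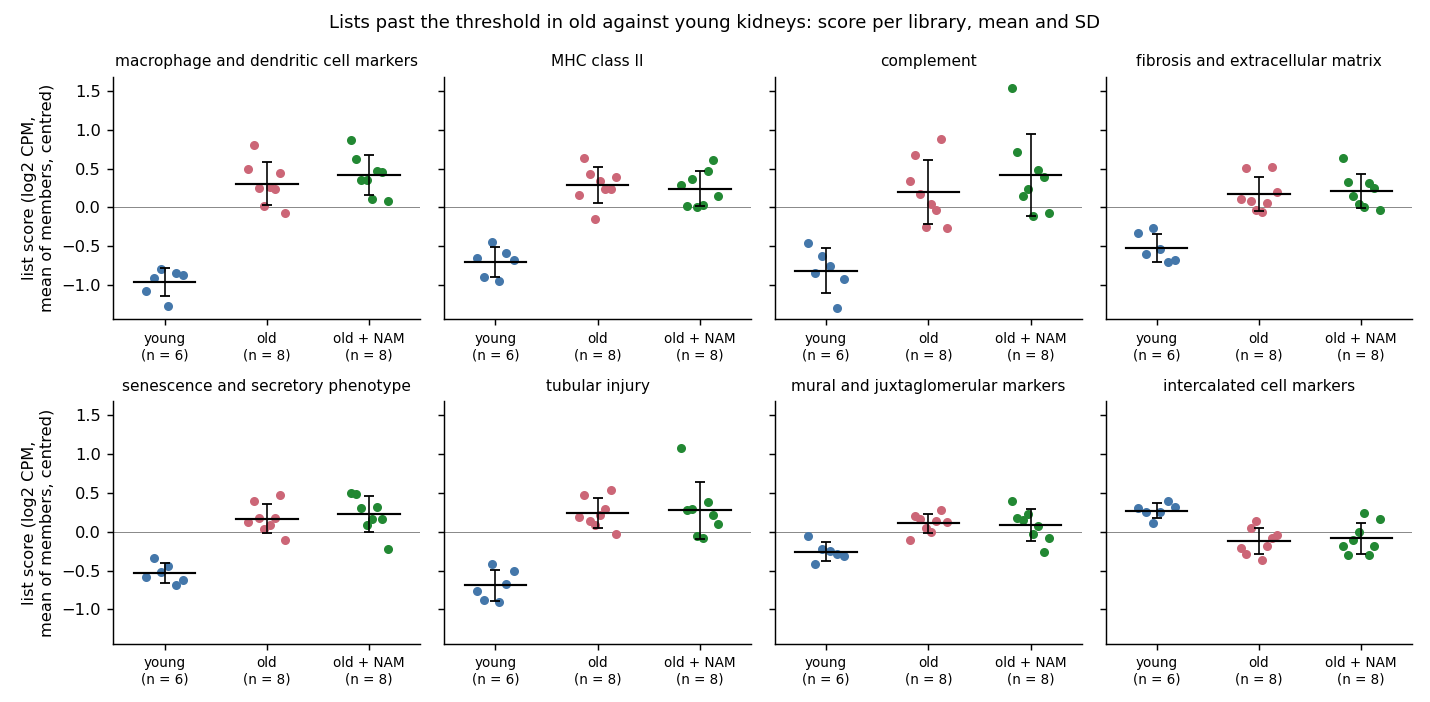
Score of 8 gene lists in each kidney, the mean over list members of log2 CPM centred per gene; points are kidneys, lines means and bars SD. In the macrophage panel all young kidneys lie at −0.786 or lower and all old kidneys at −0.0753 or higher.

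Of the kidney's own cell types, intercalated cell markers fell: 3 of 13 members passed, all downward, and 6 adjusted over the list alone (median −0.33, adjusted p = 0.0438 with an estimated correlation). Slc26a4, the chloride and bicarbonate exchanger pendrin, fell 1.82-fold (−0.87 ± 0.19, adjusted p = 0.00242). This list call was lost when any 1 of 10 kidneys was left out (young replicates 1, 2, 4, 5 or 6, old replicates 1, 2, 5 or 6, or nicotinamide replicate 3; adjusted p of 0.0504 to 0.0906), without the 4 kidneys (0.0634) and with a block for the replicate number (0.0611). Mural and juxtaglomerular markers rose in 6 of 14 members, 9 adjusted over the list alone, while 1 fell (median 0.49, adjusted p = 0.0206 with an estimated correlation). Rgs5 of pericytes (0.68 ± 0.11, adjusted p = 4.03e-05) and Tagln of smooth muscle (1.06 ± 0.20, adjusted p = 0.00135) rose, and Ren1, which encodes renin, fell (−0.75 ± 0.21, adjusted p = 0.0298, lost in 6 of 32 alternatives). Podocyte markers had 5 of 13 members past, all upward, 5 adjusted over the list alone, Cdkn1c among them (median 0.34, adjusted p = 0.0868 with an estimated correlation; 0.0466 without young replicate 6 and 0.0446 without old replicate 7). Distal and connecting tubule markers had 4 of 13 past, all downward, 4 adjusted over the list alone (median −0.17, adjusted p = 0.145 with an estimated correlation), such as Klk1, the kallikrein of the connecting tubule, 1.76-fold lower, and the calcium-binding Calb1, 1.42-fold lower. Proximal tubule S3 markers had 3 past downward and 1 upward of 10, 4 and 1 adjusted over the list alone (adjusted p = 0.226 with an estimated correlation, 0.0494 without the 4 kidneys). The monocarboxylate carrier Slc5a8 fell (−0.58 ± 0.10) and the amino acid carrier Slc6a18 rose (0.39 ± 0.09). S1 and S2 markers had 1 of 18 past downward, the transcription factor Hnf4a (−0.32 ± 0.08), and 4 adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). Loop of Henle markers had 1 of 11 past, the tight junction gene Cldn10 (−0.36 ± 0.09), 1 adjusted over the list alone (adjusted p = 0.606 with an estimated correlation), and endothelial markers 1 of 16, Egfl7 (0.48 ± 0.14), 1 adjusted over the list alone (0.129). The call of Egfl7 was lost in 3 of 32 alternatives (highest adjusted p 0.0777).

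Metabolic lists leaned downward, and with all 22 kidneys none of them passed with an estimated correlation, while some did by fry, by score or without the 4 kidneys. Nuclear genes of oxidative phosphorylation had 10 of 34 members past, all downward, and 23 adjusted over the list alone (median −0.21, adjusted p = 0.120 with an estimated correlation, 0.0494 without the 4 kidneys, fry 0.00204). Its score was lower in old by −0.23 (95% interval −0.33 to −0.14; exact permutation adjusted p = 0.00224), with 0 of 8 old kidneys above the young mean. Ndufa1 of complex I fell 1.42-fold (adjusted p = 0.000771). Fatty acid oxidation had 5 of 28 past downward, 6 down and 1 up adjusted over the list alone (adjusted p = 0.245 with an estimated correlation), among them Hadh. Cholesterol synthesis had 3 of 21 past downward, 3 adjusted over the list alone (0.195), with the synthase Hmgcs1 1.39-fold lower. Androgen-dependent kidney genes had 3 of 14 past downward, 8 adjusted over the list alone (median −0.46, adjusted p = 0.120 with an estimated correlation, 0.0230 without nicotinamide replicate 1, 0.0138 without the 4 kidneys, fry 0.00790), such as Gusb and Hsd11b1. Without the 4 kidneys 10 members fell. Their score differed by −0.53 (−0.77 to −0.30; exact permutation adjusted p = 0.00137), again with 0 of 8 old kidneys above the young mean. In the longevity and vitamin D list 3 of 12 fell, 4 adjusted over the list alone (0.206), and Kl, which encodes the ageing-related hormone klotho, fell 1.28-fold (−0.35 ± 0.10, adjusted p = 0.0217; 0.0851 without young replicate 2 and 0.0522 without old replicate 2).

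For the pathway in the series title, Nnmt, the enzyme that methylates and so clears nicotinamide, had 0 to 6 counts per young kidney and 4 to 14 per old kidney, too few for the gene-wise test. Its level was 0.382 ± 0.425 CPM (SD, n = 6) in young and 1.21 ± 0.618 CPM (n = 8) in old kidneys, a difference of 0.823 CPM (95% interval 0.203 to 1.48; exact permutation p = 0.0120, adjusted p = 0.0144). NAD synthesis genes had 2 of 16 past downward, 2 adjusted over the list alone (adjusted p = 0.260 with an estimated correlation). They were the cytosolic NAD kinase Nadk (−0.37 ± 0.09, adjusted p = 0.00645) and the mitochondrial Nadk2 (−0.60 ± 0.17, adjusted p = 0.0212, lost in 4 of 32 alternatives). Nicotinamide clearance and NAD consumption had 1 of 19 past, Parp9 (0.91 ± 0.28, adjusted p = 0.0459, lost in 13 of 32 alternatives), and 2 up and 2 down adjusted over the list alone (adjusted p = 0.840 with an estimated correlation, fry 0.217). The score of this list was 0.21 higher in old kidneys (95% interval 0.10 to 0.33; exact permutation p = 0.00133, adjusted p = 0.00308), with 8 of 8 above the young mean. Its median fold change was 0.13, and −0.02 without the 4 kidneys, so the sign of the median is not firm. Of the 4, only young replicate 6 and old replicate 7 belong to the groups compared here, and which of them moved the median was not tested. The score of NAD synthesis differed by −0.09 (−0.30 to 0.11; exact permutation adjusted p = 0.417). Methionine and one-carbon genes had 3 of 23 past downward, 4 adjusted over the list alone (0.145, fry 0.0147; score −0.17, 95% interval −0.30 to −0.04, exact permutation adjusted p = 0.0311, 0 of 8 old kidneys above the young mean), among them Gatm of creatine synthesis and Mthfd1 of folate metabolism, lost in 13 and 7 of 32 alternatives.

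In old against young, 1034 of 14683 genes passed, 572 upward and 462 downward, against 3034 at an unadjusted p below 0.05 (734 by chance). At least 2-fold, 256 rose and 25 fell, and in 387 genes the 6 young and 8 old values did not overlap (chance share 0.0666%). Of 37 lists 8 passed, 28 with the preset correlation and 22 with fry. Compared by score, which sets no list against other genes, 23 lists differed by exact permutation tests. Upward were 16: the 7 lists that passed upward with an estimated correlation and the podocyte, endothelial, T cell, B cell, lymphoid aggregate, interferon, urothelial, p53 and nicotinamide clearance lists. Downward were 7: the intercalated, S3, distal tubule, oxidative phosphorylation, mitochondrial, androgen-dependent and methionine lists. The remaining lists gave adjusted p of 0.273 for immediate early and heat shock genes (6 of 19 past upward; 8 up and 2 down adjusted over the list alone; Nr4a1 and Klf4), 0.309 for mitochondrially encoded genes (0 of 7; 3 down over the list alone), 0.361 for urothelium (0 of 7; 0 over the list alone), 0.409 for NRF2 targets (1 up and 2 down of 17; 2 and 4 over the list alone), each with an estimated correlation. It was 0.623 for the unfolded protein response (1 of 17 down, Dnajb9, lost in 15 of 32 alternatives; 0 over the list alone), 0.623 for the clock (0 of 20; 0), 0.953 for blood cells (0 of 9; 0), 0.953 for adipocytes (0 of 10; 0) and 0.993 for principal cells (0 of 12; 0), each with an estimated correlation. Their adjusted p by fry were 0.0525, 0.0697, 0.0972, 0.236, 0.495, 0.539, 0.980, 0.980 and 0.896. The adipocyte and blood lists had positive medians (0.56 and 0.02) while the test pointed downward. Without the 4 kidneys their medians were −0.45 and −0.007. Fewer genes passed without young replicate 2 (670) or young replicate 4 (668), and 1031 passed without the 4 kidneys, 831 of them shared.

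Old with nicotinamide against old asks what 14 weeks of the supplement did in the aged kidney, and 4 genes passed. S100a11, a calcium-binding protein of the S100 family, rose from 132 ± 21.3 to 189 ± 28.4 CPM (SD, n = 8 and 8; log2 fold change 0.51 ± 0.09 SE, adjusted p = 0.0110), after 87.8 ± 8.53 CPM in young kidneys, so that it moved further in the direction of age. Arf3, a small GTPase of Golgi traffic, rose 1.40-fold from 44.2 ± 4.97 to 61.8 ± 5.66 CPM (0.48 ± 0.10, adjusted p = 0.0458), against 49.96 ± 8.83 CPM in young. The ribosomal RNA gene CT010467.1 fell 1.42-fold (−0.51 ± 0.07, adjusted p = 0.000166), from 5.22% ± 0.648 to 3.74% ± 0.456 of the gene counts, with 4.38% ± 0.198 in young. The unclassified transcript Gm38319 fell 1.99-fold (−0.99 ± 0.20, adjusted p = 0.0391), from 18.9 ± 5.94 to 9.50 ± 3.21 CPM. All 8 treated kidneys lay on the stated side of the old median for each. The last 2 names were chosen after their values were seen, since the naming rule leaves out clone names.

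The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 together held 11.4% ± 0.632 of the counts in old and 9.58% ± 1.06 in treated kidneys, a difference of −1.79 percentage points (95% interval −2.74 to −0.864; exact permutation p = 0.000466, adjusted p = 0.00140), with 10.1% ± 0.362 in young. In the gene-wise test mt-Rnr2 did not pass (−0.29 ± 0.07, adjusted p = 0.197). Other genes of lowest p that did not pass were, upward, the apoptosis effector Bak1 (0.89 ± 0.22), the lipoprotein receptor Lsr (0.38 ± 0.10), the kinetochore gene Zwint (0.42 ± 0.11), Slc35e4 (1.01 ± 0.27) and the transcription factor Klf13 (0.36 ± 0.09), with adjusted p of 0.324 to 0.355. Downward they were the laminin receptor Itga6 (−0.37 ± 0.08, adjusted p = 0.168), Zfp106 (−0.37 ± 0.08, 0.197), Ppp1r13b, a cofactor of p53 (−0.89 ± 0.22, 0.324), and Vcp-rs (−0.56 ± 0.14, 0.324). Nnmt stood at 1.07 ± 0.496 CPM with nicotinamide, a difference of −0.132 CPM from old (95% interval −0.745 to 0.452; exact permutation p = 0.657, adjusted p = 0.716).

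**Figure D3:**
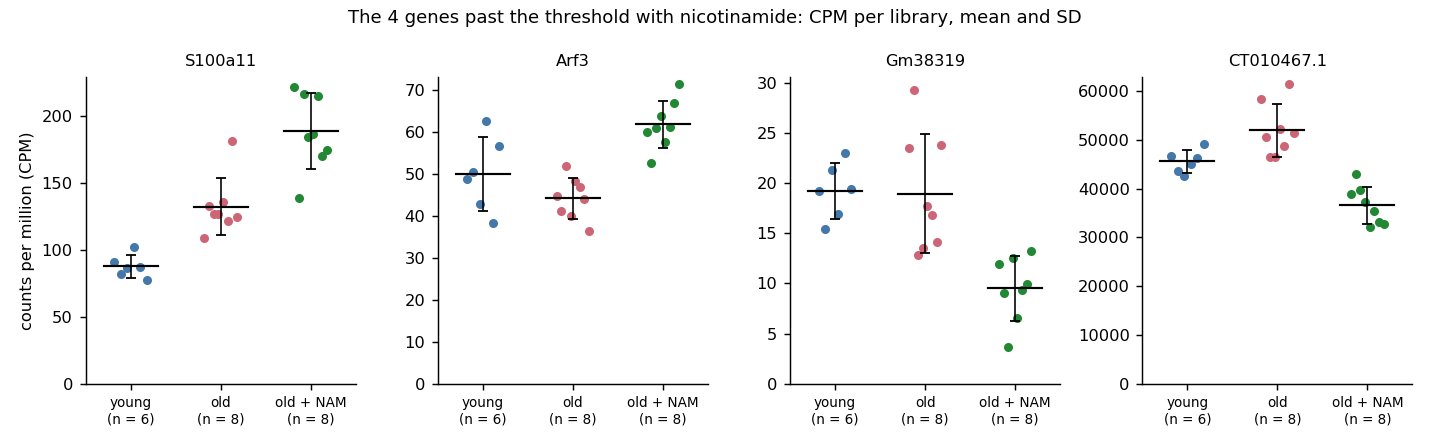
CPM of S100a11, Arf3, Gm38319 and CT010467.1 in each kidney by group; points are kidneys, lines means and bars SD, and each axis starts at 0. S100a11 stands highest with nicotinamide (189 CPM on average), and CT010467.1 lowest.

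None of the 37 lists passed with nicotinamide by camera with an estimated correlation: the count was 0, with 1 at an unadjusted p below 0.05, 3 with the preset correlation and 0 with fry. Of the 7 lists that had risen with age, 6 had mean scores close to their old level. Scores differed from old by 0.04 for fibrosis (95% interval −0.20 to 0.28, after a rise of 0.69 with age), 0.06 for senescence (−0.17 to 0.29, after 0.70), 0.04 for tubular injury (−0.24 to 0.35, after 0.93), 0.11 for macrophages (−0.18 to 0.40, after 1.26), −0.05 for MHC class II (−0.29 to 0.20, after 0.99) and −0.02 for mural cells (−0.21 to 0.16, after 0.36). Complement differed by 0.22 with the widest interval (−0.28 to 0.73, after 1.01), and by 0.06 without nicotinamide replicate 1 (−0.36 to 0.47). These intervals exclude a return by the size of the age difference in each of the 7 lists, as did those of all 16 runs that left out 1 old or treated kidney. They do not exclude a partial return, as for mural cells, where the interval reaches −0.21 after a rise of 0.36. The exact permutation adjusted p was 0.964 for each of the 7 lists. Matrix genes went both ways, from −0.36 to 0.71, with Mgp at 532 ± 86.3 and 489 ± 75.0 CPM. Havcr1 stood at 10.3 ± 4.82 and 10.3 ± 4.68 CPM. NAD synthesis genes had a median of 0.08 (−0.08 to 0.27 over 16 members) and clearance and consumption genes −0.06.

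B and plasma cell markers were lower with nicotinamide in all 17 members (median −0.88), and the score differed by −0.93 (95% interval −1.84 to −0.04; exact permutation p = 0.0420, adjusted p = 0.964). Igkc stood at 2021 ± 668 CPM in old and 1112 ± 764 in treated kidneys, and Ighg1 at 44.8 ± 41.0 and 8.30 ± 9.41. The list passed with the preset correlation (adjusted p = 3.88e-07) but had an adjusted p = 0.991 with an estimated correlation, and the lowest score, −2.07, was that of nicotinamide replicate 7. Adipocyte markers (median 2.14; preset 0.000355) and immediate early genes (median −0.20; preset 0.0418) likewise had adjusted p = 0.991 with an estimated correlation. Nicotinamide replicate 1, with 349 CPM of Fabp4, had the highest adipocyte score (3.71). The higher adipocyte markers were not confined to it: nicotinamide replicates 2 and 6 scored 3.33 and 2.09, and 7 of 8 treated kidneys had a score above the old mean of −0.45. Old scores ran from −1.63 to 2.08 and treated scores from −1.48 to 3.71, so the groups overlapped widely. Without the 4 kidneys the adipocyte median was 2.62 and the B and plasma cell median −0.66. The adipocyte score differed from old by 1.30 (95% interval −0.47 to 3.11, exact permutation adjusted p = 0.964). T cell markers had a median of 0.75, and of −0.10 without the 4 kidneys; interferon genes had 0.30, and −0.33 without them.

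The other lists had medians between −0.18 and 0.35, all with adjusted p = 0.991 with an estimated correlation: lymphoid aggregate −0.18, podocyte −0.13, cholesterol −0.10, proliferation −0.06, unfolded protein response −0.06, loop of Henle −0.05, mural −0.02, oxidative phosphorylation 0.00, fatty acid oxidation 0.00, distal tubule 0.01, S1 and S2 0.02, endothelium 0.03, methionine 0.03, principal cells 0.04, S3 0.05, NRF2 0.05, p53 0.05, longevity 0.06, intercalated cells 0.06, mitochondrial 0.07, complement 0.13, androgen 0.13, clock 0.15, blood 0.33 and urothelium 0.35. Without the 4 kidneys the medians of the urothelium, lymphoid aggregate and blood lists were 1.01, −0.66 and −0.05. With all kidneys, the median and the test differed in sign for the methionine, S1 and S2, loop, distal, oxidative phosphorylation and proliferation lists. For the unfolded protein response the median and the test pointed downward and the mean upward. Over all genes 0 members of any list passed in edgeR. Adjusted over the list alone 1 member passed in each of 6 lists. Chosen after their values were seen, these were Car2, a carbonic anhydrase (−0.29 ± 0.08), the podocyte scaffold Magi2 (−0.42 ± 0.11), Rgs5 (−0.30 ± 0.10), mt-Co1 (−0.20 ± 0.07), Gclm of glutathione synthesis (−0.24 ± 0.07), all downward, and the clock gene Nr1d1 upward (0.41 ± 0.12).

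**Figure D4:**
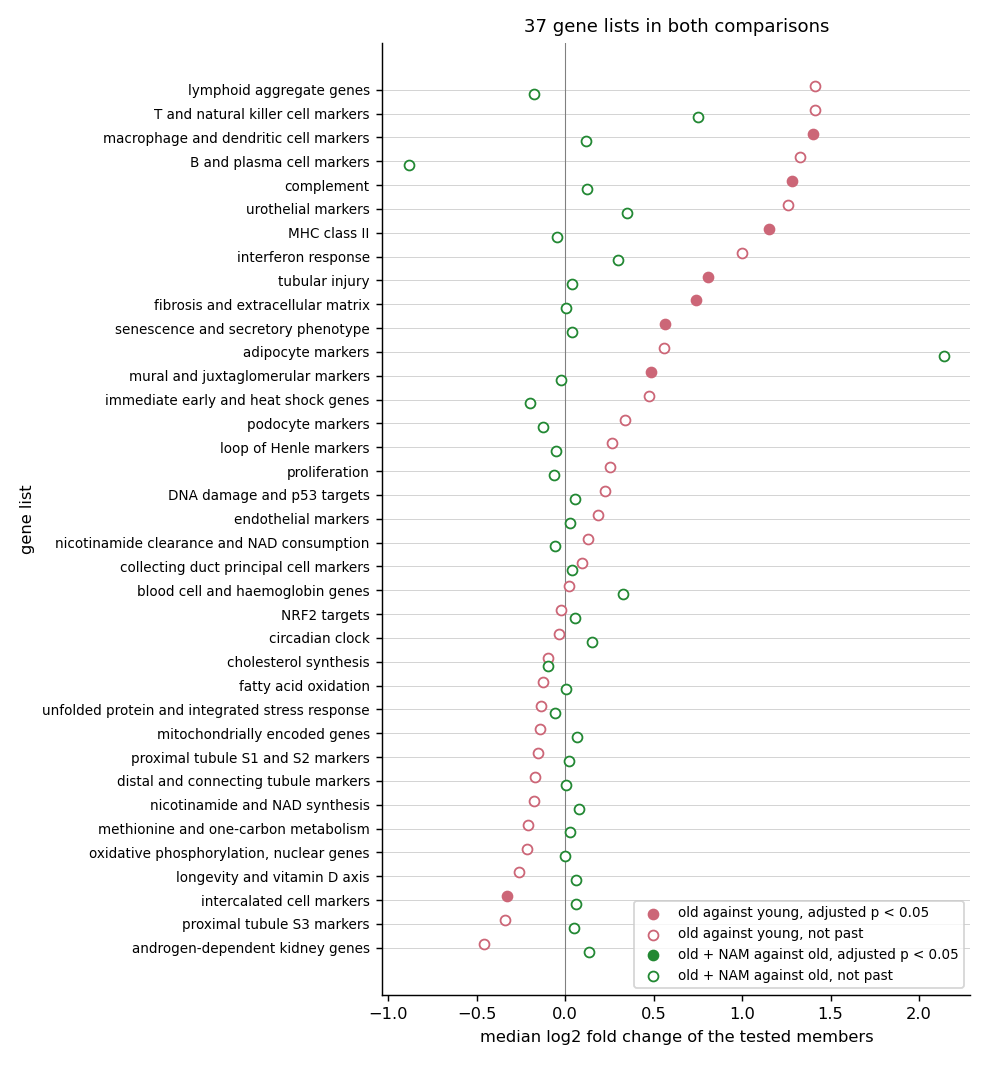
Median log2 fold change of the tested members of 37 lists, old against young and old with nicotinamide against old; filled points have an adjusted p below 0.05 with an estimated correlation. There are 8 filled points for age and 0 for nicotinamide.

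At an unadjusted p below 0.05 there were 907 genes (734 by chance) with nicotinamide, and in 4 genes the 8 old and 8 treated values did not overlap (chance share 0.0155%). DESeq2 called 11 genes, limma-voom 8, and edgeR without the 3 ribosomal RNA genes only S100a11 (adjusted p = 0.0247). CT010467.1 passed in all 31 alternatives that held it. S100a11 was lost without old replicate 1 (adjusted p = 0.0671), old replicate 6 (0.0520) or nicotinamide replicate 6 (0.0510), Arf3 in 18 and Gm38319 in 14 of 32 alternatives. Without the 4 kidneys 6 genes passed, 3 of them shared.

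Whether nicotinamide moved the age-changed genes back was asked over the 1034 genes that passed with age. Of these, 679 (65.7%) moved toward young, and tested over these genes alone 0 passed in that direction in edgeR (79 at an unadjusted p below 0.05), 1 in DESeq2 (Zwint) and 0 in limma-voom. In the direction of age 1 passed in edgeR, S100a11 (adjusted p = 0.00154 over these genes alone), 2 in DESeq2 (Car2 and S100a11) and 1 in limma-voom (S100a11). Both comparisons use the old kidneys with opposite signs, which alone makes genes appear to move back. With the 8 old kidneys split into 4 and 4, so that no kidney served both comparisons, the share of the 500 most age-changed genes that moved toward young was 51.4% on average (28.6% to 72.2% over 70 splits), against 62.2% with shared kidneys. Across genes, which are not independent replicates, the covariance of the 2 sets of fold changes was −0.0341 with shared kidneys, −0.0336 in 100 simulations without any effect (−0.0365 to −0.0316) and −0.00155 with split kidneys. In these simulations the share that moved toward young was 89.2% (85.4% to 92.4%) and the correlation −0.46, against −0.29 in the data. The simulated data hold no age changes, so both values depend on noise alone and are no reference for the data, while a covariance is not changed by adding age changes unrelated to the treatment.

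Old with nicotinamide against young compared treated old kidneys with the young reference. Havcr1 stayed 2.51 ± 0.46 above young on the log2 scale (adjusted p = 0.00117), H2-Aa 1.02 ± 0.12 (1.22e-06) and Ctxn3 −2.79 ± 0.47 (0.000315). S100a11 was higher by 1.10. In all, 1277 genes passed, 695 upward and 582 downward. Of these, 407 of the upward and 270 of the downward genes had also passed in old against young. The young kidneys serve both comparisons, which by itself makes them share genes. Lists past were macrophages (20 of 22 members up, 21 adjusted over the list alone, adjusted p = 0.00106 with an estimated correlation), MHC class II (6 of 8, 7; 0.00195), senescence (6 of 24, 12; 0.00195), fibrosis (20 of 32, 22; 0.00771), tubular injury (19 of 26, 21; 0.00997) and complement (11 of 16, 14; 0.0120). The other 31 lists did not pass with an estimated correlation, and the clock and NRF2 lists had medians, means and tests that differed in sign. With the preset correlation 25 of the 37 lists passed, with fry 19, and by exact permutation tests of the scores 17. Among those 17, mural scores differed from young by 0.34 (adjusted p = 0.0158) and intercalated scores by −0.36 (adjusted p = 0.0123). Lcn2, a secreted marker of tubular injury chosen after its value was seen, stood at 3.14 ± 2.07 CPM in young and 31.5 ± 41.6 CPM with nicotinamide (3.35 ± 0.68, adjusted p = 0.00399), with 133 CPM in nicotinamide replicate 1. Without the 4 kidneys 801 genes passed, and without young replicate 2 835 passed.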

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

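The tests that weigh explanations in this part (ribosomal RNA carry-over, ribosomal share of the counts, tubule share, fat, lymph node and blood) were chosen after the result was seen. Of 396 comparisons of a group's highest or lowest kidney with the rest of its group, over library measures, list scores and the levels of named genes, 31 found a kidney that stood apart; chance gives about 1 in 20, or 19.8. Nicotinamide replicate 1 held 7 of them, nicotinamide replicate 7 held 4, and no other kidney more than 3, so a single one carries little weight.

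Nicotinamide replicate 1 had the highest tubular injury score of its group, 1.08 against −0.08 to 0.39. Its scores of proximal tubule S1 and S2 markers (−0.51 against −0.17 to 0.09), of S3 markers (−1.02 against −0.12 to 0.22) and of androgen-dependent genes (−1.13 against −0.26 to 0.31) were the lowest. The S3 and androgen-dependent lists share members, so their scores are not separate observations. Its NAD synthesis score was also the lowest of the group, −0.32 against 0.0015 to 0.20. Hnf4a, a transcription factor of the proximal tubule, stood at 203 CPM in this kidney against 253 to 292 CPM in the others, and Itga6 at 116 against 80.9 to 94.6 CPM. Lcn2 reached 133 CPM in it. Without this kidney 9 genes passed with nicotinamide in place of 4.

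Nicotinamide replicate 7 had a T and natural killer cell score of 2.81 against −0.39 to 0.54 in the rest of its group, with 166 CPM of the chemokine Ccl5 and 16.8 CPM of the T cell receptor chain Cd3e. It also had the highest levels of Usp18 (12.9 CPM against 1.31 to 4.01) and Icam1 (38.6 against 18.5 to 23.95), and the lowest of the podocyte gene Cdkn1c (32.1 against 45.5 to 55.4). A piece of lymph node would bring B cells, but its B and plasma cell score of −2.07 was the lowest of the group, with 295 CPM of Igkc. That argues against a piece rich in B cells. Its lymphoid aggregate score of 1.33 was the highest of the group, against −1.22 to 0.90 in the others. Ccr7 was also highest in it, at 3.30 CPM, so lymphoid tissue as a source stays open. Blood left in the kidney would raise haemoglobin genes at least as much as T cell markers, but the 13 tested T cell markers, several of them near 1 CPM in other kidneys, lay 2.55 above the other 7 kidneys of the group in median (log2, pseudocount 0.5 CPM), against 0.768 to 1.55 for 4 haemoglobin genes, which argues against blood as the whole source. Immune cells drawn into this kidney by an infection may be behind it, since 23 interferon genes lay 1.87 higher in median, but the labels hold nothing on the animal and no biological explanation was tested.

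Among the old kidneys, replicate 8 had the lowest Cx3cr1 (13.1 CPM against 30.2 to 55.1), while macrophage markers as a list stood higher in old than in young kidneys. A lower share of tubule cells would raise the markers of all other cell types alike, but the macrophage score rose by 0.978 more than the endothelial score (95% interval 0.67 to 1.29; exact permutation p = 0.000333, the smallest these tests can give, n = 8 and 6), 0.981 more than the podocyte score and 0.902 more than the mural score. Fat attached to the kidney piece would bring macrophages of its own, but the 4 old kidneys with adipocyte scores at or below the young median still lay 1.07 above young kidneys (0.795 to 1.34; exact permutation p = 0.00476, n = 4 and 6). Both results argue against these explanations as the whole cause. Age itself, with more macrophages or more of these transcripts per macrophage, stays open and was not tested apart.

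With nicotinamide, the ribosomal RNA gene CT010467.1 fell and S100a11 rose. Carry-over of ribosomal RNA through library preparation could lower CT010467.1 together with mt-Rnr1 and mt-Rnr2: centred on group means, both shares had r = 0.458 over 22 kidneys (permutation p = 0.0667, adjusted p = 0.0667 over 3 relations; rho = 0.272, permutation p = 0.267). Within groups r was −0.151 in young, 0.291 in old and 0.628 in treated kidneys, and without old replicate 7 and nicotinamide replicate 1 it was 0.513 (permutation p = 0.0647), so preparation and a response of the kidney to nicotinamide cannot be told apart for CT010467.1. For S100a11, a smaller ribosomal share of the counts would raise all other genes alike. As shares of the whole library, without scaling factors, the other 14679 genes moved by 0.033 in median (SD 0.291, 5th to 95th percentile −0.413 to 0.473), and S100a11 by 0.537. A rise shared by all genes was thus small beside that of S100a11. S100a11 was picked for its change, so its place above the median was given beforehand, and 538 of the other genes rose at least as much. Leaving out the 3 ribosomal RNA genes hardly moved these fold changes and so tests nothing of this kind: S100a11 kept its call (0.509 against 0.510), while Arf3 (0.483 ± 0.098, adjusted p = 0.0653, against 0.484) and Gm38319 (−0.994 ± 0.195, adjusted p = 0.0571) lost theirs because the adjustment no longer counted CT010467.1 ahead of them.

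Other kidneys stood apart in 1 to 3 values each. In old replicate 7 the urothelial score was 2.28 against −0.67 to 0.25 in the other old kidneys, Cd4 stood at 6.91 CPM against 1.22 to 2.87 and S100a11 at 181 against 109 to 136 CPM. Old replicate 5 had the lowest Cd2 (0.18 CPM against 1.22 to 3.09) and the lowest Hmx2, a transcription factor of intercalated cells (0.730 against 2.36 to 4.41). Old replicate 6 had the highest Nnmt, 2.51 CPM against 0.548 to 1.42.

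In nicotinamide replicate 2, the deepest library with 8319865 gene counts (5663649 to 6752083 in the others of its group), Lsr was lowest at 47.0 CPM against 55.4 to 62.6, and Slc35e4 at 3.04 against 6.61 to 10.4. Vcam1 was lowest in nicotinamide replicate 5, 18.5 CPM against 31.4 to 48.0. Among the young kidneys, replicate 3 had the highest Adamts15 (87.4 CPM against 14.0 to 27.8), the lowest Klf13 (99.97 against 106 to 109) and the lowest distal tubule score (−0.024 against 0.19 to 0.31). Young replicate 2 had the lowest urothelial score (−2.58 against −0.90 to −0.12) and the lowest Ifi213 (0.150 CPM against 0.940 to 1.91). Young replicate 5 had the lowest Ephx1, a detoxifying epoxide hydrolase (13.8 CPM against 21.5 to 27.3), and the lowest Pou2f2 (7.22 against 9.91 to 11.6). Young replicate 6, the shallowest library with 3351065 gene counts against 6115567 to 7184997, had the lowest score of nicotinamide clearance and NAD consumption genes, −0.36 against −0.14 to −0.040.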

How the results depend on the processing

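Leaving out 4 kidneys or the 3 ribosomal RNA genes, and single kidneys for list scores, were alternatives chosen after seeing the data; the other alternatives and the splits of the libraries were planned. For old against young, the 1034 genes became 904 with a block for the replicate number (794 shared) and 958 to 1399 under the other planned settings of normalization, filter, tool and samples. Leaving out 1 library gave 668 to 1305; it was 668 without young replicate 4 and 670 without young replicate 2, with 639 and 642 shared. Of 75 genes that the naming rule selected for age, 48 passed in each of up to 32 alternatives that held them, 27 lost the call in at least 1 (Ighg1 in 17, Dnajb9 in 15, Parp9 and Gatm in 13 each) and 0 reversed. Ren1 (highest adjusted p 0.0841), Nadk2 (0.0811), Kl (0.0851) and Hnf4a (0.0583) were among those lost in some. Over 100 drawn splits of the kidneys into groups of these sizes, the real one included, chance could be excluded (1034 genes, at most 1 in another split).

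For nicotinamide against old, the 4 genes became 7 without the low-count filter, 11 with DESeq2, 8 with limma-voom and 1 without the ribosomal RNA genes. The first 3 called further genes and held 4, 3 and 4 of the original ones; the cause was not tested. The count was 3 with the replicate block, 3 with only both groups in the fit and 6 without the 4 kidneys. Leaving out 1 library gave 1 to 9: it gave 9 without nicotinamide replicate 1, 1 without old replicate 1 or 6 or nicotinamide replicate 6, and 2 without young replicate 1, old replicates 2, 5 or 8 or nicotinamide replicates 3, 5 or 7. CT010467.1 passed in each alternative that held it (highest adjusted p 0.0105), while the calls of S100a11 (highest 0.0671), Arf3 (0.188) and Gm38319 (0.168) were lost in 3, 18 and 14 alternatives. Itga6, Zfp106, mt-Rnr2, Lsr and Zwint passed in 4, 5, 5, 1 and 1 alternatives, and 0 named genes reversed. Over 100 drawn splits, the real one included, only the real split gave 4 genes, with at most 3 in another. That margin is small, and leaving out 1 library took the count as low as 1, so chance was not firmly excluded.

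For nicotinamide against young, the 1277 genes became 801 without the 4 kidneys (718 shared) and 1081 with the replicate block, with 974 to 1530 under the other planned settings. Leaving out 1 library gave 835 to 1438, the lowest without young replicate 2. Fewer kidneys lower the power, but what lowered these counts in particular was not tested. Chance could be excluded over 100 splits (1277 genes, at most 15 in another split).

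Of the 37 lists, 8 passed with age, 28 with the preset correlation, 22 with fry, 7 with the replicate block, which ended the call of intercalated cells (0.0611), and 13 without the 4 kidneys (7 shared). Without those kidneys S3 (0.0494), oxidative phosphorylation (0.0494), podocyte (0.0291), T cell (0.0202), interferon (0.0202) and androgen-dependent genes (0.0138) passed, and intercalated cells did not (0.0634). Members past there changed by more than 1.5 times for fibrosis (17 to 11), interferon (4 to 11), androgen-dependent (3 to 10), fatty acid oxidation (5 to 3), S1 and S2 (1 to 3), S3 (3 to 5 downward) and p53 genes (2 to 0), and 1 member more or fewer passed in a direction for both NAD lists, NRF2 targets, blood and mitochondrial genes. The preset correlation of 0.01 lay below most of the estimated ones (−0.0277 to 0.684 over lists and comparisons), and fry asks another question; the cause of the 13 was not tested. Leaving out 1 library gave 7 to 10. Intercalated cells lost their call without any of 10 kidneys, with adjusted p of 0.0504 to 0.0906. Podocytes passed without young replicate 6 (0.0466) or old replicate 7 (0.0446), T cells (0.0152) and interferon genes (0.0399) without nicotinamide replicate 7, androgen-dependent genes without nicotinamide replicate 1 (0.0230), and p53 targets without nicotinamide replicate 4 (0.0481). With nicotinamide 0 lists passed in camera, 3 with the preset correlation, and 0 with fry, with the block or with any 1 library left out. Chance could be excluded for age (8 lists, at most 1 in another of 100 splits). For nicotinamide, with 0 lists past, all 100 splits reach that count whatever the data, so they decide nothing (at most 1 in another). Leaving out 1 kidney moved the nicotinamide score differences of the 7 lists that rose with age to −0.02 to 0.09 for fibrosis, 0.02 to 0.12 for senescence, −0.07 to 0.09 for injury, −0.07 to 0.02 for mural cells, 0.04 to 0.18 for macrophages, −0.11 to 0.003 for MHC class II and 0.06 to 0.32 for complement, the lowest without nicotinamide replicate 1 except for senescence (old replicate 8) and MHC class II (old replicate 4). The lymphoid aggregate list fell under 5 members in some settings and was then not tested.

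The covariance of age and nicotinamide changes across genes went from −0.0341 to −0.00155 with the old kidneys split 4 and 4, which follows from the split, since no kidney then served both comparisons; it was −0.0345 with the other low-count filter. Depth limited Nnmt, at 0 to 14 counts per kidney. At these depths and dispersions the simulated test recovered 28.4% of genes changed 1.5-fold with nicotinamide and 64.2% of those changed 2-fold. Only the fold was varied, so whether depth or the spread between animals limited small changes was not tested. The pseudocount alternatives were not run, because the table held counts.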

Other observations

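The tests and gene choices in this part were all made after the result was seen. Among the genes that changed with age, those with the lowest p for a move back toward young under nicotinamide were Zwint, Phf12, Thsd7a, Pgm1, Itpripl2, Irf8 and Sp5. The kinetochore gene Zwint stood at 47.2 CPM in young, 35.2 in old and 47.0 in treated kidneys, a change of 0.42 ± 0.11 on the log2 scale with nicotinamide (adjusted p = 0.324). Phf12, a subunit of a histone deacetylase complex, stood at 55.1, 75.5 and 56.2 CPM (adjusted p = 0.355), and Thsd7a, a podocyte membrane protein, at 25.3, 35.4 and 26.2 CPM (adjusted p = 0.382). Pgm1 of glycogen metabolism stood at 58.2, 41.7 and 54.7 CPM (adjusted p = 0.387). Irf8, a transcription factor of macrophages, stood at 33.1, 72.2 and 56.1 CPM (adjusted p = 0.523). None of these 7 genes passed over all genes in edgeR, and since the old kidneys serve both comparisons, some genes appear to move back by chance alone.

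Adipocyte and urothelial scores rose and fell together, with Adipoq at 60.7 CPM and Psca at 49.9 CPM in nicotinamide replicate 1, and Psca at 42.1 CPM in old replicate 7. The hypothesis was that some kidney pieces held tissue of the renal hilum, where fat and the urothelium of the pelvis lie. Centred on group means, the scores had r = 0.567 over 22 kidneys (permutation p = 0.0149, adjusted p = 0.0312 over 3 relations; rho = 0.587, permutation p = 0.0101). Within groups r was −0.232 in young, 0.627 in old and 0.772 in treated kidneys. Without old replicate 7 and nicotinamide replicate 1 it was 0.298 (permutation p = 0.314), so the size of r depends on those kidneys. The rank correlation over all 22 kidneys was no weaker than r, and the hypothesis stays open.

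Androgen-dependent kidney genes were low where tubular injury genes were high, as in nicotinamide replicate 1. The hypothesis was that injured tubules lose androgen-dependent expression. The scores had r = −0.685 over 22 kidneys (permutation p = 0.0208, adjusted p = 0.0312 over 3 relations) but rho = −0.232 (permutation p = 0.324). Within groups r was −0.375 in young, −0.65 in old and −0.745 in treated kidneys. Without old replicate 7 and nicotinamide replicate 1 r was −0.00237 (permutation p = 0.993), so this relation rests on those kidneys, and the other 20 kidneys give no sign of it.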
